A study of Mus musculus with 6 samples.

How the data were processed

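Total RNA was extracted from LK cells (lineage-negative, c-Kit-positive bone marrow cells) of wild type and ASXL1-MT-KI littermates. Per the labels' protocols, libraries were made from 200 ng RNA with the NEBNext Ultra kit, which does not mark strand, and read as paired ends of 124 bp on a HiSeq instrument. The submitters' processing notes name HISAT2 2.0.4 and the mouse build mm10. The counting tool, its annotation, its use of strand, its treatment of reads that match several genes and whether pairs or single reads were counted are not given in the sources used here. The authors deposited 1 table of raw counts per gene symbol, whole numbers that had not been normalized, with 24421 rows and a column for each of the 6 libraries. Every row names a gene, and 6240 rows are 0 throughout. Columns were assigned to samples by the genotype and number in their names. Without strand and with unknown treatment of shared reads, overlapping genes, antisense genes and close paralogs, such as histones, Ear genes and zinc finger genes, are uncertain. All 10 haemoglobin rows hold 0 or 1 counts, so the haemoglobin genes could not be tested, and 13 mitochondrially encoded genes of a fixed list are not analysed here.

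The libraries held 47242076, 46875571 and 40739398 counts in wild type replicates 1 to 3 and 47579480, 44326770 and 40462168 in ASXL1-MT-KI replicates 1 to 3. The main comparison was ASXL1-MT-KI against wild type with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum of 10 counts, TMM scaling (factors 0.972 to 1.03), a robust quasi-likelihood F test with genotype as the only term, and Benjamini-Hochberg adjustment over 13548 genes at 0.05. CPM values are TMM-scaled, with the mean ± SD of 3 libraries. Standard errors of log2 fold changes are the estimate divided by the square root of F. For genes with fewer than 4 counts in a group the ratio of summed counts is given with a 95% interval, and a group at 0 is set to a floor of 3 counts over the group; both cover counting error only. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, for the 96.1% of tested genes whose symbol matched a single gene.

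Before the data were examined, the groups, the test, the alternatives, 36 gene lists and the rule for naming genes were fixed. The rule took, in each direction, the 10 genes with the lowest p and the 5 with the largest fold among those past the threshold with a mean count of at least 50 in the higher group, no overlap between groups and a symbol that is not a clone name (for the fold part also a CPM of at least 1), then Asxl1, Asxl2, Asxl3, Bap1, Gt(ROSA)26Sor, Hoxa9 and Meis1, and up to 4 members of each list by p. Lists with at least 5 tested members, 35 in all, were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives.

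Replicate numbers come from the sample titles, and littermates were used, but no label says that a number marks a litter or an experiment. The numbers were therefore checked against the counts. Across genes, which are not independent replicates, deviations from the group mean correlated between same-numbered libraries at 0.253, 0.162 and 0.391. All 3 exceed 0.1, a level fixed before the fits were compared, so the numbers were taken to pair the libraries. Wild type 2 and ASXL1-MT-KI 1 also correlated, at 0.163, no less than the 2 libraries numbered 2. The check thus does not show that the number 2 libraries form a pair. The main test kept the design fixed beforehand, without a block, and blocked values are given where they change a call or move a count, in total or in 1 direction, by over 1.5 times. No pair of libraries within a genotype agreed within sampling noise; pairs across genotypes were not compared. The design text calls the experiments biologically independent but does not say whether each library was 1 animal.

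The pipeline was tested on simulated counts with the real means and library sizes and 200 changed genes. It recovered 76.1% of 1.5-fold, 79.1% of 2-fold and 97.0% of 4-fold changes among 13548 genes, and 15 of 183 calls (8.20%) were false. Alternatives were the replicate block, DESeq2 size factors, total counts, haemoglobin genes left out, DESeq2 1.42.0, limma-voom, no filter, a filter at CPM 1 in 3 libraries, an adjusted p under 0.10, a fold of at least 1.5, leaving out each library, leaving out X inactivation and Y-linked genes, and 1 surrogate variable from sva 3.50.0. A loess correction for GC content and length of the longest transcript (96.3% of tested genes had both), the same with the block, and number 3 of both groups left out were added after seeing the data. Figures were drawn with matplotlib 3.10.9.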

Results

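RNA sequencing was carried out on bone marrow cells of C57BL/6 mice, sorted as negative for lineage markers and positive for the receptor c-Kit. This LK gate holds haematopoietic stem cells and the myeloid, erythroid and megakaryocyte progenitors. The 2 groups were wild type mice and littermates with a knock-in of mutant ASXL1, a chromatin regulator that is recurrently mutated in myeloid malignancies and in clonal haematopoiesis; the knock-in is named ASXL1-MT-KI. Each group had 3 libraries from animals 8 to 12 weeks old, described as biologically independent experiments. Libraries held 40462168 to 47579480 gene counts, and Mpo or Eef1a1, the most abundant gene in each, took 1.31% to 1.48% of them. Of 24421 gene rows, 13548 were tested, and the biological coefficient of variation between libraries of a group was 8.78%. All 6 libraries carried Y-linked transcripts, with 4053 to 5477 counts of Ddx3y, and had 4 to 29 counts of Xist, the RNA of the inactive X chromosome. The comparison asks which genes mutant ASXL1 changes in haematopoietic stem and progenitor cells.

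Genotype was the main axis of difference between the libraries. The first principal component of the 1000 most variable genes held 66.3% of the variance and put the wild type libraries between -22.3 and -20.5 and the ASXL1-MT-KI libraries between 20.8 and 22. A second component, with 14% of the variance, set number 3 of both groups, at -14.9 and -11.7, apart from the other libraries, which lay between 1.81 and 10.5. In the number 3 libraries of both groups, the list of haem and red cell membrane genes was lower by a median of -0.50 on the log2 scale, with 32 of 35 members lower than in numbers 1 and 2. G2 and M phase genes were lower in them by -0.22, while mast cell, basophil and eosinophil genes were higher by 0.38 and neutrophil granule genes by 0.21.

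**Figure D1:**
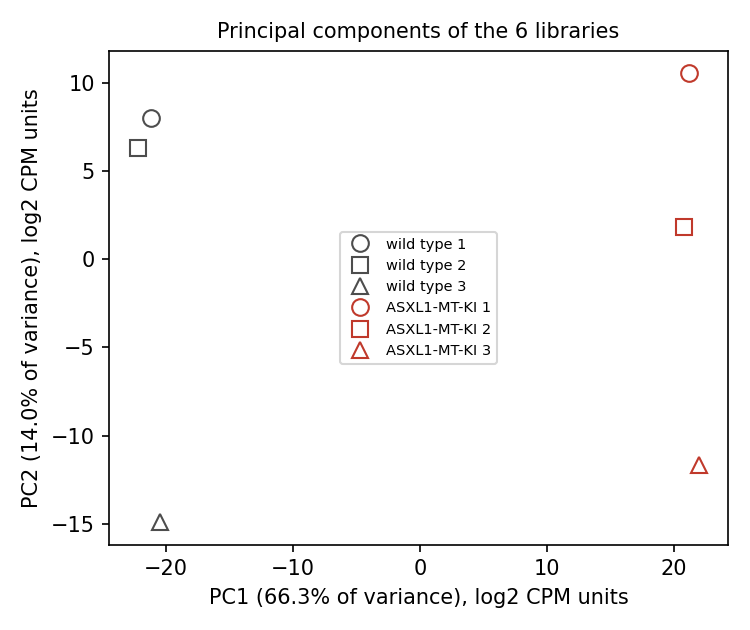
Position of each of the 6 libraries on the first principal component (x axis, 66.3% of the variance, log2 CPM units) and the second (y axis, 14%). Grey symbols are wild type and red symbols ASXL1-MT-KI libraries, and the shape gives the replicate number. The genotypes separate along the x axis, and both number 3 libraries lie at the lower end of the y axis, at -14.9 and -11.7.

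Asxl1 itself, on chromosome 2 from 153345829 to 153404007 in mm10, was higher in every ASXL1-MT-KI library. The wild type libraries had 8077, 7793 and 6703 counts and the ASXL1-MT-KI libraries 15525, 14763 and 12868. This is a rise from 170.4 ± 5.43 to 320.1 ± 8.71 CPM (counts scaled by library size; SD, n = 3 each), or 1.88-fold (log2 fold change 0.91 ± 0.047, SE; adjusted p = 9.7e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Counts per gene do not separate reads of the knock-in allele from those of the endogenous gene. Asxl2, a paralog, was at 93.4 ± 0.90 and 95.7 ± 6.03 CPM (log2 fold change 0.03, adjusted p = 0.728). Asxl3 had no test, with too few counts. Bap1, the deubiquitinase that ASXL1 activates, fell from 175.3 ± 6.41 to 151.5 ± 6.63 CPM (log2 fold change -0.21, adjusted p = 0.0241), a call that was lost when any of 4 libraries was left out, with adjusted p up to 0.0889. Gt(ROSA)26Sor, the non-coding transcript of the Rosa26 locus, stood at 0.596 ± 0.146 and 0.698 ± 0.228 CPM and did not pass (adjusted p = 0.676).

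In ASXL1-MT-KI cells 1123 genes rose and 1042 fell, together 2165 of the 13548 tested (16%), at an adjusted p under 0.05. The change reached 2-fold for 260 of the risers and 211 of the fallers, and 4-fold for 59 and 42. Rises were frequent among weakly expressed genes and falls among strongly expressed ones: in 4 equal classes of mean expression, from the lowest up, 64.7%, 69.3%, 44.9% and 14.9% of the calls were rises. How far falls prevailed in the highest class depended on the scaling. With total counts in place of TMM factors, which shifted the median log2 fold change of all genes from 0.00 to 0.05, rises made up 67.1% rather than 51.9% of all calls and 40.8% of those in the highest class. Falls still outnumbered rises in that class, at 231 against 159. With the replicate number as a block, 4132 genes passed, 30.5% of those tested (2256 rose and 1876 fell), among them 2152 of the 2165. Counts of list members that pass with the block have to be read beside this share. No label gives this pairing, which was read from the counts alone. Leaving out wild type replicate 1 gave 1128 genes, ASXL1-MT-KI replicate 2 gave 1143 and ASXL1-MT-KI replicate 1 gave 1388.

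Genes with almost no transcript in wild type cells were among the clearest rises. Evc and Evc2, neighbours on chromosome 5 (37289098 to 37336894 and 37338499 to 37425055), encode partner proteins at the base of primary cilia that act in hedgehog signalling. Evc2 went from 0.337 ± 0.087 to 32.7 ± 1.02 CPM, 95.4-fold (log2 fold change 6.58 ± 0.13, adjusted p = 1.1e-08), and Evc from 0.232 ± 0.101 to 23.4 ± 1.25 CPM, 98.7-fold (adjusted p = 8.5e-08). Ptprf, a receptor tyrosine phosphatase on chromosome 4, rose 12.3-fold to 23.9 ± 2.91 CPM. The kinesin gene Kif21a rose 9.28-fold, to 10.5 ± 1.54 CPM, and Spats2 reached 5.73 ± 1.09 CPM from 0.302 ± 0.066. Dzip1l, another gene of the ciliary base, had 305 counts against 2 in wild type, a ratio of 150 with a 95% counting interval of 41.1 to 1243. Lgi2 had 230 counts against 2, a ratio of 113 (30.9 to 939), and Sva 254 against 0, at least 83.2-fold higher against a floor of 3 counts over the group. Genes already expressed in wild type also rose. Ccnd1, which encodes cyclin D1, went from 26.5 ± 2.33 to 65.6 ± 4.56 CPM (log2 fold change 1.31 ± 0.080, adjusted p = 2.4e-05), the syndecan gene Sdc2 from 3.44 ± 0.399 to 13.6 ± 0.689 CPM, and Sh3pxd2b from 24.3 ± 1.39 to 56.7 ± 2.89 CPM.

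The clearest falls were of genes with different roles. Nfkbiz, an inducible regulator of NF-kB target genes, fell from 287.7 ± 18.2 to 120.8 ± 7.67 CPM (log2 fold change -1.25 ± 0.064, adjusted p = 9.7e-06). Birc3, an inhibitor of apoptosis, fell by 0.99 on the log2 scale, Zc3h12a, an endonuclease that degrades inflammatory mRNAs, by 1.08, and the RNA-binding protein gene Arid5a by 0.94. Map3k8, a kinase upstream of ERK in innate signalling, went from 11.7 ± 0.235 to 3.75 ± 0.351 CPM. Kdm6b, a demethylase of the Polycomb mark on histone H3, fell from 406.2 ± 30.5 to 202.5 ± 4.41 CPM (adjusted p = 2.1e-05), and Smad7, an inhibitor of TGF-beta signalling, from 167.8 ± 12.1 to 84.5 ± 6.44 CPM. S1pr1, the sphingosine phosphate receptor that guides cell egress, fell by 1.51, Smim3 by 1.33, and the protocadherin gene Pcdh7 reached 1.73 ± 0.343 CPM (log2 fold change -3.03). The largest falls by fold were of Tjp1, a tight junction scaffold gene (log2 fold change -4.77 ± 0.40, from 23.5 ± 9.05 to 0.854 ± 0.143 CPM), Ramp3 (-3.95 ± 0.60, on 10, 2 and 0 counts in ASXL1-MT-KI, and -5.77 to -3.43 on leaving out 1 library), Rgs16 (-3.07 ± 0.32) and Irg1 (-2.94 ± 0.27), the gene of the enzyme that makes itaconate.

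**Figure D2:**
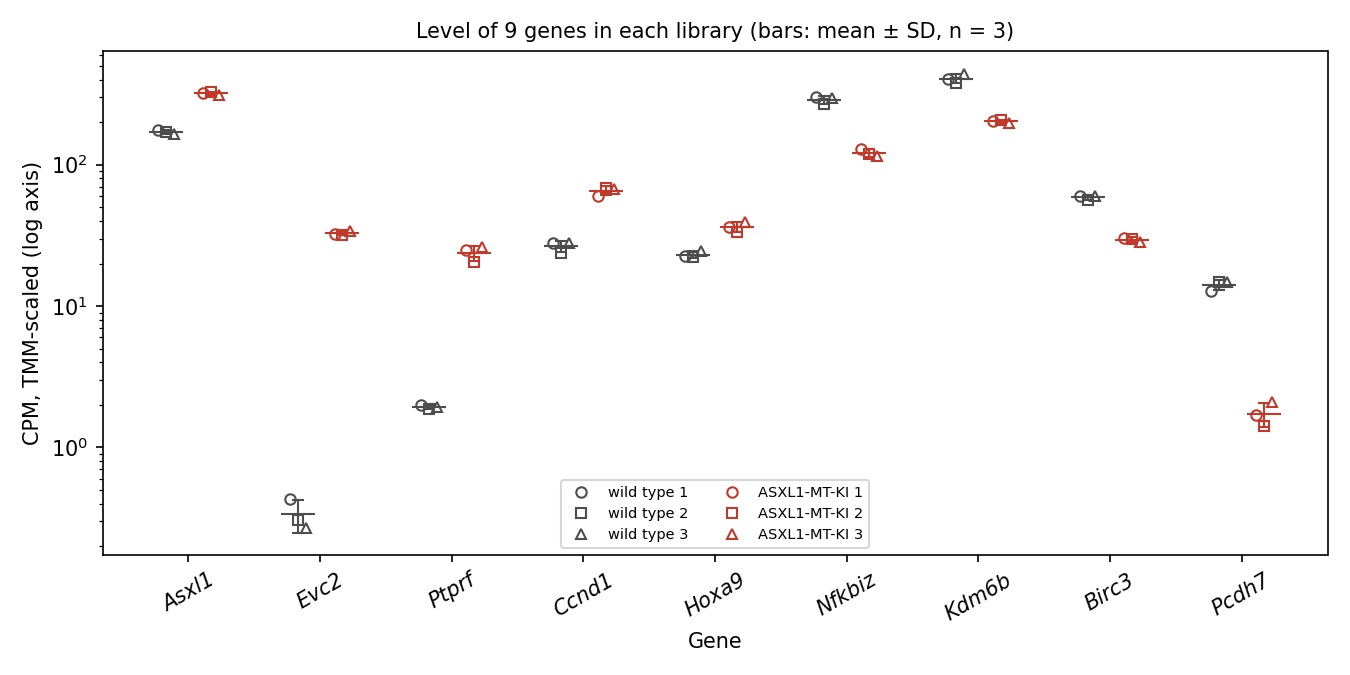
CPM with TMM scaling (y axis, log scale) of 9 genes (x axis) in the 3 wild type libraries (grey) and the 3 ASXL1-MT-KI libraries (red). The symbol shape gives the replicate number, and horizontal bars with whiskers are the mean ± SD of 3 libraries. The genotypes do not overlap for any of these genes, with Evc2 at 0.337 ± 0.087 CPM in wild type and 32.7 ± 1.02 CPM in ASXL1-MT-KI.

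Genes of NF-kB signalling and inflammation were lower in ASXL1-MT-KI cells, and no other list had as large a median change in the main test. Without ASXL1-MT-KI replicate 3 the B lymphoid median was lower, at -0.86 against -0.82. Of 34 tested members, 22 fell, or 26 adjusted over the list alone. None rose in the main edgeR test, also at an unadjusted p under 0.05, or in limma-voom, and 1 rose in DESeq2. With the block 3 rose and 24 fell, and with numbers 1 and 2 only 2 rose and 22 fell. The median log2 fold change was -0.80 (camera adjusted p = 5.4e-14; adjusted p = 0.647 with an estimated correlation, and adjusted p = 0.0117 for direction with fry). Beside Nfkbiz and Birc3, the subunit gene Nfkb2 fell from 105.0 ± 11.6 to 62.9 ± 1.76 CPM and the receptor gene Tlr2 from 49.7 ± 4.0 to 28.3 ± 1.62 CPM. Immediate early genes, which respond within minutes to stimulation, followed: 13 of 31 fell, 17 adjusted over the list alone, none rose in the main edgeR test (also at an unadjusted p under 0.05), DESeq2 or limma-voom, 1 rose without ASXL1-MT-KI replicate 1, and the median was -0.52 (camera adjusted p = 3.5e-10; adjusted p = 0.746 with an estimated correlation and 0.0727 with fry). Egr3 went from 24.0 ± 4.87 to 6.93 ± 1.94 CPM, the nuclear receptor gene Nr4a2 from 76.4 ± 3.48 to 25.9 ± 5.44 CPM and Gadd45b from 77.0 ± 13 to 37.9 ± 4.55 CPM. Fos and Dusp1, chosen after their values were seen, differed between replicate numbers rather than genotypes: Fos was at 1237, 1210 and 397 CPM in wild type libraries 1 to 3 and at 1212, 1396 and 534 CPM in ASXL1-MT-KI (adjusted p = 0.909). The list as a whole was lower by -0.30 in the number 3 libraries, and the 13 falls became 8 without wild type replicate 1 or without ASXL1-MT-KI replicate 2. With the block 19 fell and 1 rose. Gadd45b did not pass with numbers 1 and 2 only, a choice made after seeing the data.

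Interferon-stimulated genes and cytokine receptor signalling genes were also lower. Of 47 interferon-stimulated genes 11 fell and none rose in the main edgeR test (12 and 2 adjusted over the list alone, 2 rises at an unadjusted p under 0.05, 1 in DESeq2 and 0 in limma-voom). With total counts 2 rose, and 1 rose after the GC and length correction and without ASXL1-MT-KI replicate 1. The median was -0.20 (camera adjusted p = 0.00108; adjusted p = 0.746 with an estimated correlation and 0.0727 with fry). Ifi44 fell by 1.59, Oas2 by 1.10, Rsad2 by 1.09 and Trim25 by 0.39 on the log2 scale. With the block, 18 fell and 6 rose, and without wild type replicate 1 the falls numbered 5. In the PI3K, AKT and cytokine receptor list 12 of 42 fell, also adjusted over the list alone, and none rose in the main edgeR test (also at an unadjusted p under 0.05), DESeq2 or limma-voom. With the block 1 rose and 14 fell, and with numbers 1 and 2 only 1 rose and 11 fell. The median was -0.08, or -0.03 with total counts and without wild type replicate 3 (camera adjusted p = 0.0017; adjusted p = 0.746 with an estimated correlation; adjusted p = 0.0133 with fry). Among the members that fell, the receptor gene Flt3 went from 123.9 ± 12.0 to 79.1 ± 4.90 CPM, the kinase gene Pim1 from 480.6 ± 29.5 to 259.1 ± 27.9 CPM and Cish, a STAT5 target, by 1.49 on the log2 scale. Apoptosis regulators went both ways, with 5 of 28 higher and 7 lower past the threshold, the same adjusted over the list alone. The median was 0.00, negative with DESeq2 size factors, and the mean -0.10. The list was not called by camera (adjusted p = 0.432) but was lower by fry (adjusted p = 0.0129; with the block, 0.0618). The survival factor gene Mcl1 fell from 649.8 ± 50.1 to 421.4 ± 34.9 CPM, Bbc3, which encodes the pro-apoptotic protein PUMA, by 0.71 and Birc2 by 0.35; without wild type replicate 1 or ASXL1-MT-KI replicate 2, the 12 calls became 6, with 1 and 0 rises. Rises numbered 2 and 3 without ASXL1-MT-KI replicates 1 and 3, and the median ran from -0.05 without ASXL1-MT-KI replicate 1 to 0.03 without wild type replicate 3.

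Red cell genes were higher in ASXL1-MT-KI cells as a group, though few passed singly. In the list of haem synthesis and red cell membrane genes 34 of 35 members were higher, with a median log2 fold change of 0.35 (camera adjusted p = 1.4e-06; adjusted p = 0.746 with an estimated correlation), and 4 passed, also adjusted over the list alone: the anion exchanger gene Slc4a1 (2.60 ± 0.062 to 5.58 ± 0.577 CPM), Uros, Gypc and Ppox. The Gypc and Ppox calls were lost without wild type replicate 1 or ASXL1-MT-KI replicate 1 or 2, and the Uros call without wild type replicate 1. The count was 28 with the replicate number as a block, 24 with numbers 1 and 2 only, 7 with total counts and in DESeq2, 1 without wild type replicate 1 and 2 without ASXL1-MT-KI replicate 1 or 2. The median was 0.22 without wild type replicate 3. The same list was lower in the number 3 libraries of both groups by more than it differed between genotypes. The 10 haemoglobin rows held at most 1 count in any library and were not tested, so globin levels cannot be read from these counts. Erythroid transcription regulators were not called as a list (1 of 17 rose, 2 fell, 2 and 3 adjusted over the list alone; median 0.04; camera adjusted p = 0.795): Bach1, a haem-regulated repressor, fell by 0.54, Foxo3 by 0.27, and Myb rose by 0.20 on the log2 scale. Of these, the Foxo3 call was lost without ASXL1-MT-KI replicate 2 (adjusted p = 0.0609), and the Myb call when any of 4 libraries was left out (adjusted p up to 0.0782). In the list 6 rose and 3 fell with the block, 3 rose with total counts, 2 rose in DESeq2 and with numbers 1 and 2 only, none rose without wild type replicate 1 or ASXL1-MT-KI replicate 1, and 1 fell without ASXL1-MT-KI replicate 2. Its median ran from -0.04 without wild type replicate 3 to 0.15 without wild type replicate 2.

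Megakaryocyte and platelet genes fell more often than they rose, with 8 of 28 lower and 3 higher (10 and 3 adjusted over the list alone) and a median of -0.14 (camera adjusted p = 0.0237; adjusted p = 0.746 with an estimated correlation). The thrombin receptor gene F2r fell by 0.87 and Plek by 0.79, while Serpine2 rose by 0.54 on the log2 scale. The list call was lost when any of 4 libraries was left out (adjusted p up to 0.0818, without ASXL1-MT-KI replicate 2) and with the stricter filter (adjusted p = 0.0685). With the block 6 rose and 12 fell. The median was -0.07, -0.08 and -0.26 without wild type replicate 1, wild type replicate 2 and ASXL1-MT-KI replicate 1, and -0.09 with total counts. In the neutrophil granule list 2 of 28 rose and 1 fell, the same adjusted over the list alone (median 0.10, camera adjusted p = 0.226). Padi4, which encodes a histone-modifying enzyme of neutrophils, rose from 14.9 ± 1.12 to 29.4 ± 2.80 CPM, and Anxa1 fell by 0.46. With the block this list was called higher (12 rose and 3 fell, adjusted p = 0.0337; 0.709 with an estimated correlation and 0.191 with fry), as it was without wild type replicate 3 (adjusted p = 0.00594). Rises numbered 4 with total counts and in limma-voom, 5 in DESeq2 and with numbers 1 and 2 only, 5 without wild type replicate 3, 4 without ASXL1-MT-KI replicate 2 and 1 without wild type replicate 1 or 2 or ASXL1-MT-KI replicate 1; without wild type replicate 2 the falls numbered 2. The median was 0.06 and 0.17 without wild type replicates 2 and 3, 0.04 without ASXL1-MT-KI replicate 3, 0.15 with total counts and 0.16 with numbers 1 and 2 only. Monocyte and macrophage genes split, with 2 of 30 rising and 6 falling (3 and 7 adjusted over the list alone; median 0.03; adjusted p = 0.760): the fibronectin gene Fn1 rose by 1.37, while the chemokine receptor gene Ccr2 fell by 0.41 and Ccl9 by 0.49. Nr4a1 fell by 1.29 but did not pass with the block (adjusted p = 0.0688) or with numbers 1 and 2 only, and without wild type replicate 1 or ASXL1-MT-KI replicate 1 the 8 calls became 4, 1 rise and 3 falls. In this list 10 rose and 8 fell with the block and 6 and 7 with numbers 1 and 2 only, rises numbered 4 with total counts and without wild type replicate 3, and 1 without ASXL1-MT-KI replicate 2. Its median ran from -0.05 to 0.12, without ASXL1-MT-KI replicates 3 and 1. Of 18 dendritic cell and MHC class II genes, 1 rose and 3 fell, the same adjusted over the list alone (median -0.15, adjusted p = 0.157; 0.0469 without ASXL1-MT-KI replicate 3), among them Runx2, lower by 0.62, and Flt3. With the block 2 rose and 3 fell. The median was -0.09, -0.29 and -0.07 without wild type replicates 1 to 3, -0.03, -0.04 and -0.35 without ASXL1-MT-KI replicates 1 to 3 and -0.10 with total counts.

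Mast cell, basophil and eosinophil genes were lower as a list (median -0.26, camera adjusted p = 0.00412; adjusted p = 0.746 with an estimated correlation), though 2 of 22 fell singly, also adjusted over the list alone. The median was -0.07 without wild type replicate 3, -0.15, -0.16 and -0.56 without ASXL1-MT-KI replicates 1 to 3 and -0.40 with numbers 1 and 2 only. The members that fell were Ear1 and Ear6, near-identical ribonuclease genes whose counts depend on how shared reads were assigned. The Ear1 call was lost with the block (adjusted p = 0.0549) and the Ear6 call without ASXL1-MT-KI replicate 1 (adjusted p = 0.0636) or 3. The count of falls was 6 with the block, in limma-voom and without ASXL1-MT-KI replicate 3, 4 with numbers 1 and 2 only and in DESeq2, where 1 rose, and 1 without wild type replicate 1 or 2. B lymphoid genes had the lowest median of the lineage lists, -0.45, and 5 of 20 fell, 7 adjusted over the list alone (camera adjusted p = 0.00881; adjusted p = 0.746 with an estimated correlation). The members that fell were weakly expressed, such as Vpreb1 (1.04 ± 0.147 to 0.442 ± 0.103 CPM), except Dntt, the terminal transferase gene (53.5 ± 11.4 to 23.5 ± 4.86 CPM), whose call was lost with the block (adjusted p = 0.0935), with numbers 1 and 2 only and without wild type replicate 1 or 3 or ASXL1-MT-KI replicate 2. The Vpreb1 call was lost without ASXL1-MT-KI replicate 2. Falls numbered 1 without wild type replicate 1, 2 without ASXL1-MT-KI replicate 2, where 1 rose, 10 without ASXL1-MT-KI replicate 3 and 8 with numbers 1 and 2 only. With the block 2 rose and 7 fell, and 2 rose without wild type replicate 3. The list was not called with the stricter filter (adjusted p = 0.110), and its median was -0.86 without ASXL1-MT-KI replicate 3 and -0.76 with numbers 1 and 2 only. In the T and NK list 3 of 17 fell, also adjusted over the list alone (median -0.12, adjusted p = 0.296), led by the co-receptor gene Cd28 (4.71 ± 0.496 to 1.87 ± 0.204 CPM). The count was 1 without ASXL1-MT-KI replicate 2, 2 rose and 2 fell without wild type replicate 3, and 3 rose and 5 fell with the block. The median ran from -0.27 to 0.02, without ASXL1-MT-KI replicates 3 and 2.

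Stem cell genes moved in both directions. Of 46 members 7 rose and 15 fell, 8 and 19 adjusted over the list alone, with a median of -0.14, or -0.09 with total counts (camera adjusted p = 0.0134; adjusted p = 0.746 with an estimated correlation), and the list was not called without ASXL1-MT-KI replicate 2 (adjusted p = 0.0861). Rises numbered 4 without wild type replicate 1 or ASXL1-MT-KI replicate 1. Procr, the surface receptor used to enrich stem cells, went from 4.39 ± 0.819 to 1.61 ± 0.309 CPM, and Cish fell as above. Hoxa9, a homeobox gene of self-renewing progenitors, rose from 23.1 ± 1.20 to 36.4 ± 2.91 CPM (log2 fold change 0.65 ± 0.077, adjusted p = 7.1e-04), while Meis1, its cofactor, fell from 61.7 ± 5.51 to 48.4 ± 3.09 CPM (adjusted p = 0.0135; 0.0542 without ASXL1-MT-KI replicate 2). Among HOX cluster genes and cofactors 7 of 17 rose and 4 fell (9 and 4 adjusted over the list alone), with a median of 0.51 that did not pass as a list (camera adjusted p = 0.0743; 0.0212 without ASXL1-MT-KI replicate 2 and 0.0257 with no filter). Hoxb3 rose from 2.07 ± 0.409 to 4.83 ± 0.117 CPM and Hoxa7 from 8.99 ± 0.911 to 16.2 ± 1.48 CPM, and the cofactor gene Pbx3 fell from 6.42 ± 0.365 to 2.97 ± 0.243 CPM; without wild type replicate 1 the 11 calls became 7 (4 rises), and falls numbered 2 without ASXL1-MT-KI replicate 2 and with numbers 1 and 2 only. Within the list of ASXL, BAP1 and Polycomb members 4 of 43 rose and 6 fell, the same adjusted over the list alone (median -0.03, and 0.02 with total counts; adjusted p = 0.441). Beside Asxl1 and Kdm6b, the Polycomb gene Bmi1 fell from 70.9 ± 3.13 to 54.5 ± 1.0 CPM and Cbx6 rose from 58.5 ± 4.92 to 80.3 ± 1.52 CPM; without ASXL1-MT-KI replicate 2 the 10 calls became 6, 3 in each direction. The median was -0.02 without ASXL1-MT-KI replicate 1 or 2.

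**Figure D3:**
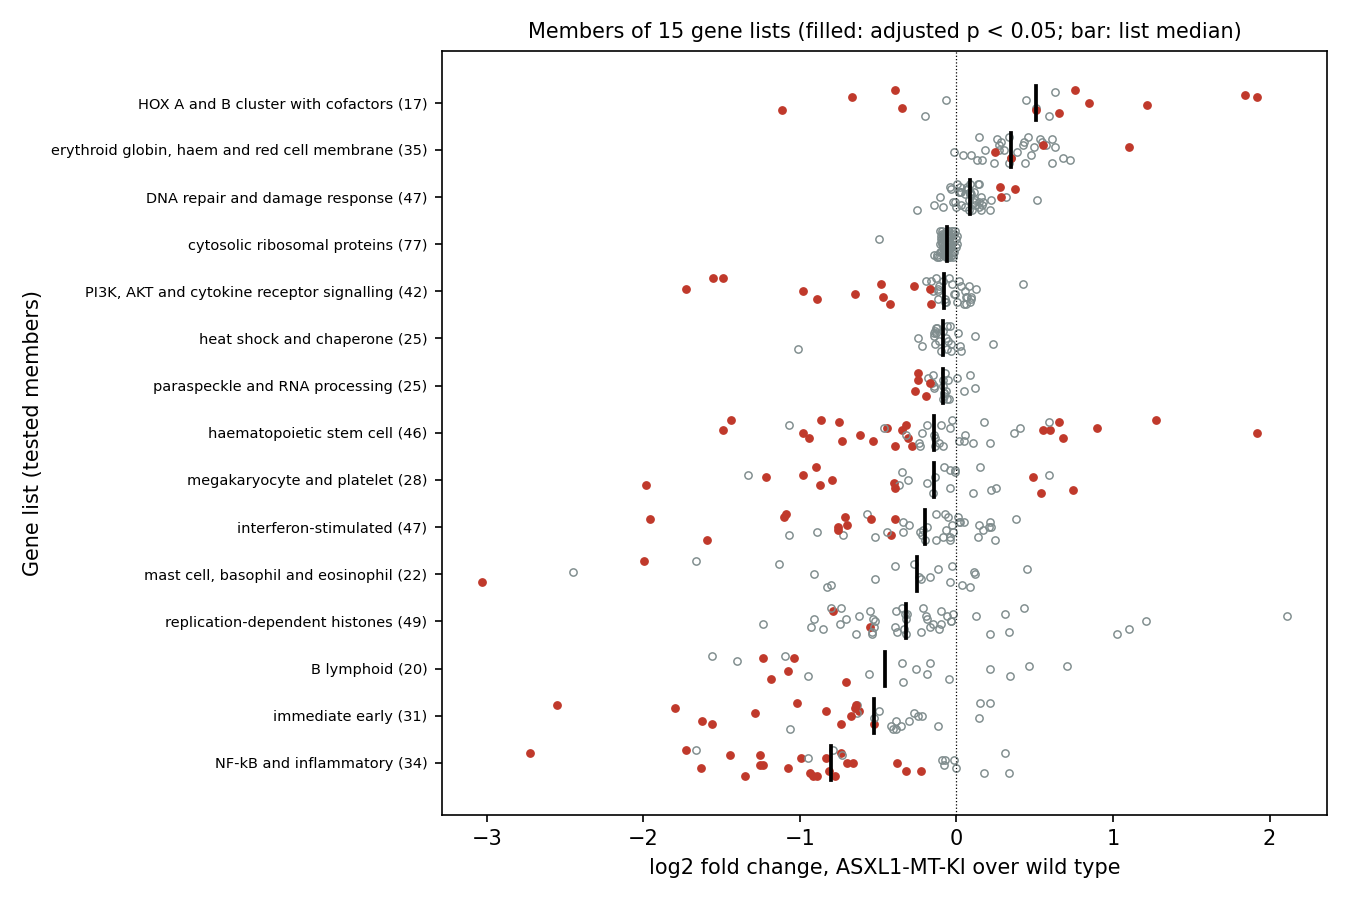
Log2 fold change of ASXL1-MT-KI over wild type (x axis) for the tested members of 15 gene lists (y axis, member number in brackets): the 14 called by camera with a preset correlation and the HOX list. Each point is a gene, filled red where its adjusted p was under 0.05, and black bars are list medians, from -0.80 for NF-kB genes to 0.51 for the HOX list.

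Cell cycle lists hardly moved. No G2 and M phase gene of 50 passed in the main edgeR test, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05, although 44 were higher (median 0.07, camera adjusted p = 0.0583). With the block, where 30.5% of all tested genes passed, 14 rose and 1 fell. The list was then called (camera adjusted p = 0.00233, 0.709 with an estimated correlation and 0.217 with fry). The same held with total counts and without wild type replicate 1 or 2 or ASXL1-MT-KI replicate 3 (camera adjusted p = 6.3e-04 to 0.0167). It was also called with no filter (camera adjusted p = 0.0288) and after the GC and length correction (0.0491, and 0.00288 with the block). The median was 0.13 without wild type replicate 2, where 1 rose, -0.00 without wild type replicate 3, where 1 fell, 0.04, 0.03 and 0.11 without ASXL1-MT-KI replicates 1 to 3 and 0.12 with total counts, and with numbers 1 and 2 only 2 rose and 1 fell. Of 50 S phase genes 2 rose and 1 fell, and none passed adjusted over the list alone (median 0.00, positive with total counts; adjusted p = 0.953). With the block 6 rose and 3 fell, with total counts 5 rose and none fell, and after the GC and length correction 2 rose and 3 fell. The count was 2 without wild type replicate 2, 1 without wild type replicate 3 and with numbers 1 and 2 only, and 0 without wild type replicate 1 or any ASXL1-MT-KI replicate. DNA repair genes were higher as a list (median 0.08, or 0.14 with total counts, 38 of 47 higher, camera adjusted p = 0.0134; adjusted p = 0.746 with an estimated correlation), and 3 rose, 1 adjusted over the list alone, led by Xrcc2 (16.4 ± 0.235 to 21.3 ± 1.65 CPM). The list was not called without ASXL1-MT-KI replicate 2 (adjusted p = 0.0989). With the block 9 rose and 1 fell, with total counts 5 rose, and without wild type replicate 1 or ASXL1-MT-KI replicate 2 the count was 1. Replication-dependent histones had a median of -0.32 (camera adjusted p = 0.00495; adjusted p = 0.746 with an estimated correlation), with 40 of 49 lower and 2 that fell, none adjusted over the list alone, among them the linker histone gene Hist1h1c (88.4 ± 10.5 to 60.3 ± 7.55 CPM), whose call was lost without wild type replicate 3 (adjusted p = 0.0516), with numbers 1 and 2 only and with 1 surrogate variable. Their transcripts share long stretches of sequence, and the list was not called without wild type replicate 1 (adjusted p = 0.0918). It was also not called after the GC and length correction with the block (adjusted p = 0.0839). Its median was -0.13 without wild type replicate 1 and -0.55 with numbers 1 and 2 only. With the block 2 rose and 7 fell, with numbers 1 and 2 only 1 and 10, and 1 and 9 without ASXL1-MT-KI replicate 3. The count was 1 without wild type replicate 1 or ASXL1-MT-KI replicate 1 or 2. Among p53 targets and senescence genes 4 of 29 rose and 11 fell, 7 and 12 adjusted over the list alone (median -0.02, and 0.04 with total counts; adjusted p = 0.226). Zmat3 rose from 6.35 ± 0.644 to 11.9 ± 0.554 CPM and Phlda3 from 2.17 ± 0.298 to 5.44 ± 0.632 CPM, while Plk3 fell by 0.81 on the log2 scale. With the block 8 rose and 12 fell, and with total counts 7 and 9. Its median ran from -0.05 without wild type replicate 3 to -0.01 without wild type replicate 2 and was -0.06 after the GC and length correction.

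Ribosomal protein genes, at 7.43% to 7.91% of all counts, were mostly lower by a small amount: 75 of 77 were lower, none passed in the main edgeR test, DESeq2 or limma-voom, 1 had an unadjusted p under 0.05, and the median was -0.06, or -0.01 with total counts (camera adjusted p = 8.5e-04; adjusted p = 0.776 with an estimated correlation; 0.0582 without wild type replicate 1). With the block or numbers 1 and 2 only 2 fell. The median was -0.04 without wild type replicate 1 and -0.10 without wild type replicate 3, where 5 fell. Rpl30 lay further down than the rest, at -0.73 to -0.35 on leaving out 1 library. Ribosome biogenesis genes had the same median of -0.06 (adjusted p = 0.0583). None of 40 passed in the main edgeR test or limma-voom, 2 passed in DESeq2 and 7 had an unadjusted p under 0.05. They were called lower as a list with the block (8 fell, adjusted p = 0.0282; 0.709 with an estimated correlation and 0.145 with fry), and without wild type replicate 3, ASXL1-MT-KI replicate 1 or ASXL1-MT-KI replicate 2 (adjusted p = 5.4e-04 to 0.0406). They were also called lower after the GC and length correction (camera adjusted p = 0.0264, and 0.00951 with the block) and with numbers 1 and 2 only (0.00743). The count was 5 without wild type replicate 3, 2 without ASXL1-MT-KI replicate 1 and after the GC and length correction, 6 with numbers 1 and 2 only and 1 with DESeq2 size factors. Their median was -0.03 without wild type replicate 2, -0.09 without wild type replicate 3 and -0.01 with total counts. Paraspeckle and RNA processing genes were lower (median -0.09, or -0.03 with total counts, camera adjusted p = 0.0053; adjusted p = 0.746 with an estimated correlation), with 5 of 25 falling and 7 adjusted over the list alone. The splicing factor gene Zrsr2 fell from 62.5 ± 1.25 to 51.9 ± 1.79 CPM. With the block 7 fell and 1 rose. The count was 1 without wild type replicate 1, ASXL1-MT-KI replicate 1 or ASXL1-MT-KI replicate 2, and 2 without ASXL1-MT-KI replicate 3 and with total counts. Heat shock genes had a median of -0.08 (camera adjusted p = 0.0271; adjusted p = 0.776 with an estimated correlation), 20 of 25 were lower, and none passed in the main edgeR test or limma-voom (1 in DESeq2, 5 at an unadjusted p under 0.05). The call was lost without wild type replicate 2 (adjusted p = 0.660), without wild type replicate 1 or ASXL1-MT-KI replicate 2 or 3 (up to 0.0589), and with the stricter filter (0.0605). With the block 5 fell, with numbers 1 and 2 only 4 and after the GC and length correction 1. The median was -0.03 without wild type replicate 2, where 2 rose, -0.14 without wild type replicate 3, where 7 fell, -0.14 with numbers 1 and 2 only and -0.03 with total counts. The unfolded protein response list was not called (median -0.05, adjusted p = 0.0994; 0.0181 to 0.0466 without wild type replicate 1, wild type replicate 3 or ASXL1-MT-KI replicate 3), and 2 of 25 fell, also adjusted over the list alone, led by the stress gene Ddit3 (49.2 ± 5.23 to 34.3 ± 1.0 CPM), and 1 passed without wild type replicate 1 or ASXL1-MT-KI replicate 1 or 2. The median ran from -0.09 without ASXL1-MT-KI replicate 3 to -0.02 without wild type replicate 2, where 1 rose, and was -0.00 with total counts.

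No metabolic list was called by camera in the main test, though mTORC1 and amino acid response genes leaned lower. No nuclear gene of oxidative phosphorylation passed out of 75 in the main edgeR test, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 (median 0.01, adjusted p = 0.476; 0.0466 without wild type replicate 1). With the block, with total counts and after the GC and length correction 1 rose, and the median ran from -0.04 without wild type replicate 3 to 0.05 without wild type replicate 1. In glycolysis 4 of 24 rose and 4 fell, 4 and 7 adjusted over the list alone (median -0.04, and 0.02 with total counts; adjusted p = 0.448): Pfkfb4 and the lactate exporter gene Slc16a3 each rose by 0.73, and the glucose transporter gene Slc2a1 fell by 0.54. With the block 5 rose and 7 fell. With total counts and without ASXL1-MT-KI replicate 3 the falls numbered 2. The median ran from -0.07 without ASXL1-MT-KI replicate 3 to -0.02 without wild type replicate 3 and was -0.08 after the GC and length correction. The 8 calls became 4 without wild type replicate 1 and 5 without wild type replicate 2 or ASXL1-MT-KI replicate 1 or 2. Of 30 mTORC1 and amino acid response genes 23 were lower, 2 rose and 5 fell, the same adjusted over the list alone (median -0.05, adjusted p = 0.0709), with Gpt2 higher by 0.56. The list was called lower without wild type replicate 3 (adjusted p = 0.0045) or ASXL1-MT-KI replicate 1 (0.0406), after the GC and length correction (0.0391; 0.0315 with the block) and with numbers 1 and 2 only (0.0117). With the block 3 rose and 9 fell, and the list was not called (adjusted p = 0.0643). The median was -0.08 without ASXL1-MT-KI replicate 3 and after the correction, -0.09 with numbers 1 and 2 only and -0.00 with total counts. The 7 calls became 2 and 3 without wild type replicates 1 and 2, and 4, 1 and 4 without ASXL1-MT-KI replicates 1 to 3. In the antioxidant list 2 of 35 rose and 4 fell, the same adjusted over the list alone (median 0.06, adjusted p = 0.409), with Me1 higher by 1.86 and the thioredoxin reductase gene Txnrd1 lower by 0.32. With the block 10 rose and 6 fell, with total counts 7 and 1 (median 0.11), and 4 and 2 without wild type replicate 2. The 6 calls became 2, 1 in each direction, without wild type replicate 1 or ASXL1-MT-KI replicate 1 or 2. The median was 0.09 and 0.01 without wild type replicates 1 and 3 and 0.04 after the GC and length correction. Cholesterol synthesis genes split, with 2 of 25 rising and 4 falling, the same adjusted over the list alone (median 0.03, adjusted p = 0.908). The 6 calls became 3 without wild type replicate 1 or ASXL1-MT-KI replicate 2, and the median ran from -0.01 to 0.09, without wild type replicates 2 and 3.

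The remaining lists, among them markers of stromal cells outside the gate, were not called by camera in the main test. In the stromal, endothelial and adipocyte list 1 of 17 rose and 2 fell, the same adjusted over the list alone (median -0.21, adjusted p = 0.133; 0.0344 without ASXL1-MT-KI replicate 1), and 0 passed without ASXL1-MT-KI replicate 1 or 2 and 1 without wild type replicate 1. Falls numbered 1 without wild type replicate 2 or 3 or ASXL1-MT-KI replicate 3 and in limma-voom, and 0 with total counts and numbers 1 and 2 only. With the block 1 rose and 4 fell. Imprinted growth regulators had 3 of 11 higher and 1 lower past the threshold (4 and 2 adjusted over the list alone; median 0.09; adjusted p = 0.60), led by the cell cycle inhibitor gene Cdkn1c, which rose from 1.33 ± 0.312 to 3.23 ± 0.233 CPM, and Grb10, which fell by 0.52. With the block 5 rose and 3 fell, and without wild type replicate 1 or 3 or ASXL1-MT-KI replicate 2 the count was 2, 1 in each direction. Leaving out ASXL1-MT-KI replicate 3 left 1 that rose and 2 that fell. The median ran from -0.11 without wild type replicate 2 to 0.21 without ASXL1-MT-KI replicate 3 and was 0.29 with numbers 1 and 2 only. None of 5 X inactivation and Y-linked genes passed in the main edgeR test or limma-voom, against 2 at an unadjusted p under 0.05 and 2 in DESeq2, 1 in each direction (median 0.02, adjusted p = 0.795). With the block 2 rose and 1 fell, after the GC and length correction 2 passed, and 1 passed with numbers 1 and 2 only and without wild type replicate 2 or ASXL1-MT-KI replicate 1 or 3. Their median ran from -0.02 without ASXL1-MT-KI replicate 3 to 0.24 without wild type replicate 1. Over all lists, 14 of 35 were called, 2 higher and 12 lower, 17 with the block, and none with an estimated correlation (lowest adjusted p = 0.647). The same test with the preset correlation called up to 17 lists when the 6 libraries were split into groups of 3 that mixed the genotypes. No gene passed in any of those other splits, where the genotype difference adds to the spread within groups.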

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

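Alternatives with the GC and length correction, with numbers 1 and 2 only, with a block combined with another list test, and for lists total counts and no filter, were chosen after seeing the data. The main test gave 2165 genes, 1123 higher and 1042 lower. With the replicate block it gave 4132, 2256 and 1876, and with 1 surrogate variable 3981, 2147 and 1834. The GC and length correction with the block gave 4539, 2177 and 2362. Of the main calls, 2152, 2155 and 2150 passed in the same direction in these 3 fits. Asking for a fold of at least 1.5 left 887, 504 and 383, by its construction fewer. Leaving out 1 library gave 1128 to 2257 genes, 534 to 1216 higher and 587 to 1041 lower, with fewer libraries in the test; the lowest counts came without wild type replicate 1 (1128) and without ASXL1-MT-KI replicate 2 (1143), and the cause of their difference from the others was not tested. The remaining alternatives lay between 2014 genes with the stricter filter and 2430 with the GC and length correction, apart from an adjusted p under 0.10 (3118); leaving out haemoglobin genes removed no tested gene and is no test. Asxl1 was higher in all 19 alternatives (log2 fold change 0.88 to 0.96, adjusted p 1.6e-50 to 2.3e-04). Lists called numbered 14, 17 with the replicate block, 11 with the stricter filter, which ended the calls of megakaryocyte and platelet, B lymphoid and heat shock genes, 16 with no filter, 15 with total counts, 17 after the GC and length correction with or without the block (with it the histone call was lost), 18 with numbers 1 and 2 only, 12 to 18 without 1 library, 3 with fry and 4 with fry and the block, and 0 with an estimated correlation, with or without the block (lowest adjusted p = 0.647 and 0.388). Fry asks a different question. Without the block it called only the NF-kB, the PI3K, AKT and cytokine receptor, and the apoptosis lists. With the block it called the NF-kB, immediate early, interferon-stimulated and PI3K, AKT and cytokine receptor lists. Among lists not called, the medians of erythroid regulators, monocyte, T and NK, oxidative phosphorylation, S phase, G2 and M phase, apoptosis, cholesterol, X and Y and imprinted genes changed sign without at least 1 library, so no direction is read from them. Over 158 other named genes and 19 alternatives, 2697 of 2984 values stayed on the same side of the threshold, 160 lost the call and 127 gained it. None was reversed where the main test or the alternative passed. Direction was not compared where neither passed, and there it could change. Eif2s3y, for example, ran from -0.11 to 0.13 on leaving out 1 library. The block ended 4 calls, of Nr4a1, Ear1, Dntt and Herpud1, and no other call of a named gene; for lists it added 3 calls and ended none. Of 121 named genes called, 38 lost the call without at least 1 library. In simulated counts at these depths a 1.5-fold change was recovered in 76.1% of cases and a 4-fold change in 97.0%, over all expression levels together.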

Other observations

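Symbol families and their comparison with random lists, and the tests of mature cells, handling, chromosome region and stromal cells below, were chosen after the results were seen. Zinc finger genes with Zfp symbols rose more often than other genes in ASXL1-MT-KI cells: 62 of 331 rose and 15 fell, with a median log2 fold change of 0.16 (Fisher's exact test, adjusted p = 2.2e-07 over 292 tests of 146 families). Random lists matched on mean expression held 40.04 rises on average, and none of 10000 held as many as 62 (permutation p = 1e-04, the smallest they can give). Matched lists were drawn only for Zfp, Map and Tmem genes, the families that passed Fisher's test on the same calls. Both tests treat genes as independent, so neither p measures spread between libraries. Zfp354a went from 0.0910 to 0.673 CPM, Zfp462 from 1.94 to 5.22 CPM and Zfp397 from 26.9 to 37.7 CPM, while Zfp36l2, an mRNA decay factor that is not of the DNA-binding class, fell from 1608 to 1164 CPM. The rises numbered 110 with the replicate block, 61 with DESeq2 size factors, 78 with total counts and 62 after the GC and length correction, but 22 without wild type replicate 1, 16 without ASXL1-MT-KI replicate 2 and 35 without ASXL1-MT-KI replicate 3. These genes are related in sequence, and shared reads were not resolved here.

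Genes with Map symbols, a mix of MAP kinase cascade members and microtubule-associated proteins, fell in 14 of 39 cases (Fisher's exact test, adjusted p = 8.2e-05), against 3.21 on average in matched random lists (permutation p = 1e-04). Genes with Mapk symbols formed a separate family of 15, of which 1 rose and 2 fell. Beside Map3k8, Map2k3 went from 153.9 to 112.0 CPM. With total counts 7 fell, and the count was 5 without wild type replicate 1 or ASXL1-MT-KI replicate 2, 8 without wild type replicate 3 and 7 without ASXL1-MT-KI replicate 1. Tmem genes rose in 29 of 174 cases (Fisher's exact test, adjusted p = 0.0213), against 17.9 in matched lists (permutation p = 0.0049), and the count was 8 and 16 without wild type replicates 1 and 2 and 10, 9 and 14 without ASXL1-MT-KI replicates 1 to 3.

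The 6 libraries make 10 splits into groups of 3, so no share of splits can fall under 0.05. The real split gave 2165 genes and the highest other 0, also among the 3 others that part every same-numbered pair. Every other split mixes the genotypes, so the genotype difference adds to the spread within its groups. Few or no genes could pass there, and the 0 gives no chance level for the 2165. For lists the real split called 14 and the highest other 17, and 7 of the 10 splits called at least 14; the 3 others that part every pair called up to 15. Camera with a preset correlation thus called as many lists between mixed groups of these libraries as between the genotypes. The mixed groups hold the genotypes in unequal numbers, so their list calls are not free of genotype either.

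The falls of NF-kB and immediate early genes were weighed against mature cells in the wild type sort, which the lineage gate removes, handling, and GC and length bias. Bootstrap intervals here and below resample the genes of a list, not the libraries, so they hold no spread between libraries. The median of 56 neutrophil, monocyte and macrophage markers was 0.066 (95% bootstrap interval -0.026 to 0.25). It lay above the bound of -0.40, which is 0.5 times the NF-kB median. That of the 37 markers below the level of the called members was 0.27 (-0.03 to 0.58). On leaving out 1 library the neutrophil list median stayed at or above 0.04 and the monocyte list median at or above -0.05. These values argue against neutrophils, monocytes or macrophages as the whole cause. Mpo, a most abundant gene of the libraries, is among the markers, so they are not limited to mature cells. GC content and length bias is argued against as the whole cause, since 34 of the 35 called members (97.1%) stayed called after the correction and 33 with the block. With numbers 1 and 2 only the median over 65 members was -0.69 (-0.84 to -0.50), against -0.66 with all libraries. Of the 35 called members 27 were still called, and 32 with the block. Both genotypes have a number 3 library, so a response shared by these libraries cancels between genotypes and could not be tested this way. The values argue only against a response that differs between the number 3 libraries as the whole cause. By the same bound B lymphoid cells (median of 20 markers -0.45, -1.06 to -0.18) and T or NK cells (17 markers, -0.12, -0.61 to 0.27) stay open, since both intervals span it, as does a handling difference between the genotypes, which cannot be told apart from genotype: the 11 members lower in the number 3 libraries had a median change 0.19 above that of the other 54 (-0.49 against -0.69, permutation p = 0.313, two-sided). An effect of mutant ASXL1 on basal inflammatory signalling may underlie the pattern and was not tested apart from these.

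Of the 59 rises of at least 4-fold, 51 were of genes in the lowest of 4 equal classes of mean expression. Large falls lay there too, with 35 of the 42 of at least 4-fold. A linked region around an altered locus is argued against as the common origin of the rises: 56 of the 59 had coordinates, on 18 chromosomes, and the fullest window of 20 Mb, on chromosome 15, held 5 of them (8.93%). Stromal, endothelial or fat cells in the ASXL1-MT-KI sort would raise their own list, whose median was -0.21 (95% bootstrap interval -0.43 to -0.06, 17 genes). In it 1 gene, Plvap, rose and 2 fell. Weakly expressed markers were not looked at apart, as they were for mature cells. The median therefore cannot exclude a small share of such cells, and most of the rises are of weakly expressed genes. After the GC and length correction 100% of the 59 stayed called, with and without the block. Derepression of silent genes by the mutant protein may be a candidate explanation, which these tests leave untested.

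The falls among strongly expressed genes could come from the scaling of the libraries. In the highest of 4 equal classes of mean expression 14.9% of calls were rises with TMM and 14.3% with DESeq2 size factors, but 40.8% with total counts, above the bound of 35% set before this was computed. With total counts falls still outnumbered rises in this class (231 against 159), and rises made up 67.1% of all calls. The contrast between this class and all calls thus remained under that scaling. GC and length bias is argued against as the source of these falls, which numbered 366 before the correction and 522 after it, with 64 and 65 rises. The share of rises was 11.1% after the correction (18.9% with the block). Whether strongly expressed genes fell or weakly expressed genes gained a larger part of the RNA cannot be read from counts without an external standard, so small falls of abundant genes, ribosomal proteins among them, remain open.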
